A study of Mus musculus with 8 samples.

How the data were processed

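Bulk RNA sequencing was carried out on femoral bone shafts of 8 male mice aged 24 weeks, 4 wild-type (WT) and 4 homozygous for a deletion of Girk3 (KO, gene symbol Kcnj9). Per the labels' protocols, the bone ends were removed, the marrow was flushed out with buffered saline, total RNA was extracted from homogenised bone with a phenol reagent and a column kit, and libraries were made with the NEBNext Ultra II RNA kit. All 8 mice are labelled C57BL6. The labels state 4 mice per group, so each library was taken as 1 mouse. The groups and the replicate numbers 1 to 4 were taken from the sample titles.

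The authors deposited 1 table of whole-number read counts per Ensembl gene. Per the submitters' processing notes, the tools named are bcl2fastq 2.17, STAR 2.5.2b and featureCounts from Subread 1.5.2, with genome build mm10. The role and settings of each tool, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from overlapping genes, antisense partners and near-identical family members can therefore not be told apart. The table holds 49315 gene IDs. Of these, 48970 matched GENCODE M21 on GRCm38, the same build as mm10, which gave symbols, coordinates, exon lengths and GC content, and the 345 IDs without a symbol took between 0.0312% and 0.0501% of the counts of a library.

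The total per library ranged from 30087749 to 36553713 counts. At this depth 3 counts over the 4 libraries of a group, taken as the floor for a gene with no count in that group, equal 0.0215 CPM. This floor covers counting error only. Counts of each pair of libraries were compared by a chi-square statistic over genes with at least 100 counts. It was at least 32.4 per degree of freedom for every pair, so no library was a repeat of another.

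KO and WT were compared with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with robust dispersion, TMM factors and the filterByExpr filter, with group as the only term. Adjusted p values are Benjamini-Hochberg values over the 17450 genes that passed the filter, with a threshold of 0.05. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 4 mice. Single values per library were compared by a two-sided exact permutation test over the 70 arrangements of 8 libraries, which cannot give a p below 0.0286. Log2 CPM values used a prior count of 2.

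Gene lists were written before the data were examined, as were the groups, the test, the rule for named genes and most of the alternative settings. They comprise 20 lists of bone biology and signalling, 15 lists of markers of cell types that bone can hold and 5 technical lists, and 25 genes stand in more than 1 list. Each of these 40 lists was tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 40 lists, and again with an estimated correlation. A list's level in a library is the mean log2 CPM of its members. The position test was a two-sided Fisher's exact test of called against other genes within 10 Mb of Kcnj9.

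The named genes are Kcnj9, up to 12 called genes per direction with a known symbol and at least 1 CPM, and, since fewer than 20 genes were called, the genes with the smallest p up to 20 in all, given as not passing. In each list, up to 4 called members or else the 2 members with the smallest p were eligible, as were the called genes near Kcnj9 and the sex-check genes. A gene named outside this rule is identified as chosen after its values were seen.

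Settings fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, DESeq2 size factors, library totals without TMM, no low-count filter, a stricter filter of at least 1 CPM in at least 4 libraries, the replicate number as a block, library sizes without dominant genes, a muscle score, a marrow score or a surrogate variable (sva 3.50.0) as a covariate, each library left out in turn, a test against a fold of 1.2, other list tests, and windows of 5 and 20 Mb. Settings chosen after seeing the data were removal of the exon length trend, with or without GC content, by loess offsets of span 0.3 per library, the joint omission of WT replicate 4 and KO replicate 4, a newer quasi-likelihood method, a threshold of 0.10, and an exact test of list levels.

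The pipeline was tested on simulated data drawn from the means, dispersions and library sizes of this comparison, with 4 libraries per group. Over 17191 genes, edgeR recovered 10.4% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 100% of those changed 4-fold, and 5.83% of its calls were genes left unchanged. DESeq2, over 15757 genes, recovered 17.9%, 73.1% and 100%, and 29.1% of its calls were genes left unchanged. With a simulated length trend and no changed gene, over 17198 genes, 10 genes and 4 lists were called, against 2 genes and 0 lists once the trend was removed.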

Results

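Gene expression was measured by bulk RNA sequencing in femoral shaft bone of 24-week-old male mice, 4 wild-type (WT) and 4 lacking Girk3 (KO). Girk3, the product of Kcnj9, is a subunit of G protein-gated potassium channels that open downstream of Gi/o-coupled receptors. The series title ties the deletion to osteoblast maturation and bone mass, and the expression comparison asks which genes differ in adult bone without the channel subunit. The libraries held 33470000 ± 2750000 counts in WT and 31830000 ± 651000 in KO (SD, n = 4 each), a difference within the spread between mice (exact permutation p = 0.314). Levels are given as CPM, counts scaled to library size.

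The targeted gene was barely detected in either genotype. Kcnj9 (ENSMUSG00000038026, chromosome 1, 172320501 to 172329318, minus strand, GRCm38) had 7, 6, 6 and 23 counts in WT replicates 1 to 4, and 0, 8, 4 and 7 counts in KO replicates 1 to 4. These counts correspond to 0.281 ± 0.169 CPM in WT and 0.157 ± 0.120 CPM in KO (SD, n = 4 each), which overlapped (exact permutation p = 0.371). Kcnj9 fell below the low-count filter, and in the edgeR fit without the filter its log2 fold change was -0.88 (SE 0.69, adjusted p = 0.630). The labels do not say which part of Kcnj9 was deleted, so its counts check nothing about the genotypes. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were expressed in all 8 libraries, with Ddx3y at 90.3 ± 10.5 CPM in WT and 109 ± 8.49 CPM in KO (SD, n = 4 each). Xist, which is transcribed from the inactive X chromosome in females, was at most 0.353 CPM in 7 libraries and 2.32 CPM in WT replicate 1.

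**Figure D1:**
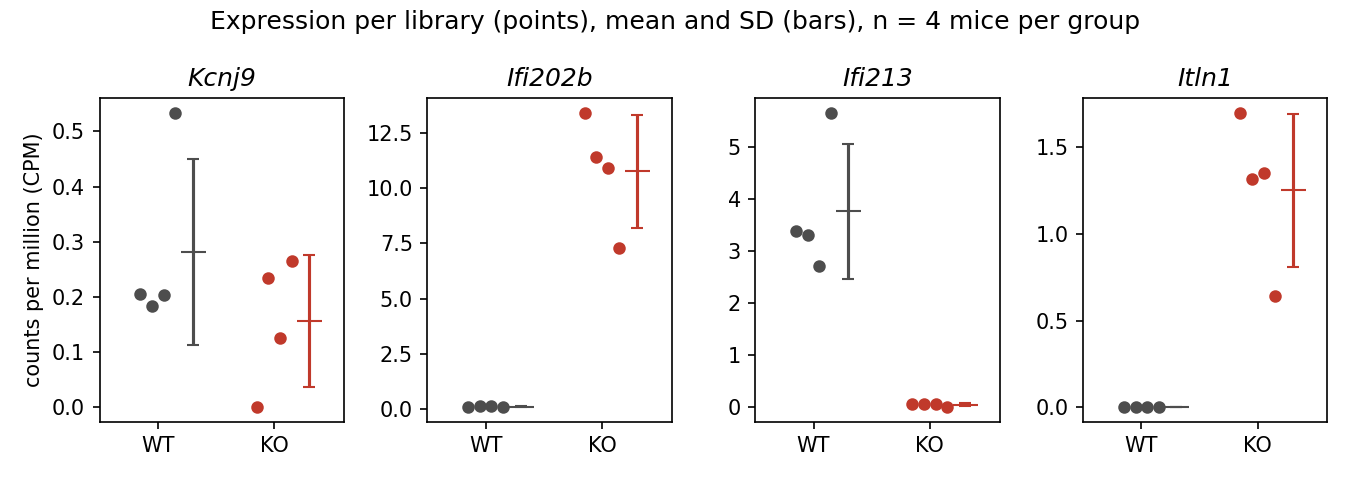
CPM (vertical axes, each panel with its own linear scale) of Kcnj9, Ifi202b, Ifi213 and Itln1 in the 4 WT and 4 KO libraries. Points are libraries and bars are mean and SD: Kcnj9 overlaps between groups, Ifi202b is at 0.110 CPM in WT and 10.7 CPM in KO, Ifi213 at 3.75 CPM in WT and 0.0465 CPM in KO, and Itln1 without a count in WT.

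Bone of KO mice differed from WT bone in 2 genes, both members of the interferon-inducible p200 family of DNA-binding proteins. Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744) rose from 0.110 ± 0.0227 CPM in WT to 10.7 ± 2.56 CPM in KO (SD, n = 4 each). Ifi213 (ENSMUSG00000073491, chromosome 1, 173566283 to 173599274) fell from 3.75 ± 1.30 CPM in WT to 0.0465 ± 0.0311 CPM in KO (SD, n = 4 each). The groups did not overlap for either gene: Ifi202b had 3 to 4 counts per WT library and 192 to 418 per KO library, and Ifi213 had 80 to 243 and 0 to 2. The log2 fold changes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 6.59 (SE 0.29, adjusted p = 8.25e-06) for Ifi202b and -6.17 (SE 0.47, adjusted p = 0.000847) for Ifi213. The family's members resemble each other, and reads shared between them could have been split by the counting, so the level of each single member is uncertain.

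A further 18 genes had the smallest p values without passing, with edgeR adjusted p between 0.0644 and 0.0714, 15 of them higher and 3 lower in KO. Of these, limma-voom called 18 and DESeq2 17, Itln1 having no adjusted p in DESeq2, and edgeR called 18 without the low-count filter, with each of the 3 covariates or without both replicates 4. In each other edgeR refit at most 1 of them passed. Itln1 (chromosome 1, 171518122 to 171535294), a carbohydrate-binding lectin, had no count in any WT library (below a floor of 0.0215 CPM) and 53, 45, 43 and 17 counts in KO replicates 1 to 4 (edgeR adjusted p = 0.0644). Atp5mpl, a small subunit of ATP synthase, was at 110 ± 10.5 CPM in WT and 222 ± 32.8 CPM in KO, with a log2 fold change of 1.02 (SE 0.14). Romo1 (0.99), Tomm7 (0.92), Malsu1 (0.91), Fmc1 (0.88) and Ndufc2 (0.82) had log2 fold changes in the same direction. Lrtm1 (1.26), Fuom (0.89), Cops9 (0.92), Gm38158 (1.33), Cuta (0.68), Churc1 (0.64), the small heat shock gene Hspb3 (0.92) and Tmem160 (0.78) also had positive log2 fold changes. The genes lower in KO were Sned1 (-1.35), the centrosomal Cep170 (-0.63) and the calcium channel gene Cacna1e (-1.14). The 15 higher genes had 339 to 7939 exonic bases and the 3 lower genes 9491 to 25228. Most of their directions thus went with the trend of fold changes with exon length given below. Lrtm1 (7939 bases) and Churc1 (5693 bases) went against it, since the deciles of their lengths had median log2 fold changes of -0.135 and -0.0775. With the length and GC trend removed, 0 of the 18 passed, but they were chosen as not passing the main test. This result therefore says nothing about the trend.

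Of the 17450 genes tested, 3172 had an unadjusted p under 0.05, 1673 higher and 1499 lower in KO, where 872 would be expected by chance. The count of 2 depended on the method, with 994 genes called by DESeq2, 705 by limma-voom with quality weights, and, by edgeR, 493 at a threshold of 0.10, 71 without a low-count filter and 1113, 1248 and 1328 with a muscle, marrow or surrogate variable covariate, Ifi202b and Ifi213 always among them. Libraries WT replicate 4 and KO replicate 4 lay at the ends of the first principal component (53.5 and -60.5, 33.5% of variance). Without both, edgeR called 458 genes. Without KO replicate 4 alone it called 4, the others being Itln1 (adjusted p = 0.0214) and Mir703 (adjusted p = 0.00855), named here after its values were seen.

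Both called genes lay on chromosome 1 within 2 Mb of Kcnj9. Ifi213 was 1.26 Mb and Ifi202b 1.65 Mb from Kcnj9, and Itln1, which did not pass, was 0.798 Mb away on the other side. Of the other genes named above as not passing, Cep170 and Gm38158 lay 4.45 and 4.51 Mb from Kcnj9, on the side of the called genes. Cacna1e, Sned1 and Cops9 also lay on chromosome 1, more than 10 Mb from Kcnj9, and the rest of them on other chromosomes. Beyond 10 Mb, 6.67% of the chromosome 1 genes had an unadjusted edgeR p under 0.01, against 6.69% on other chromosomes. Within 10 Mb of Kcnj9, 2 of 215 tested genes were called, against 0 of 17194 elsewhere (two-sided Fisher's exact p = 0.000152). The test takes genes as independent, while these 2 belong to 1 family, lie close together and may share reads. Its p may therefore overstate the clustering. In edgeR 22 of the 215 near genes and 1150 genes elsewhere in the genome had an unadjusted p under 0.01. Elsewhere DESeq2 called 975 genes and limma-voom 687. With the larger sets of calls of DESeq2 (19 of 190 near genes) and of edgeR with the marrow covariate (23 of 215) the position test did not pass, with Fisher's exact p of 0.0528 and 0.0606.

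**Figure D2:**
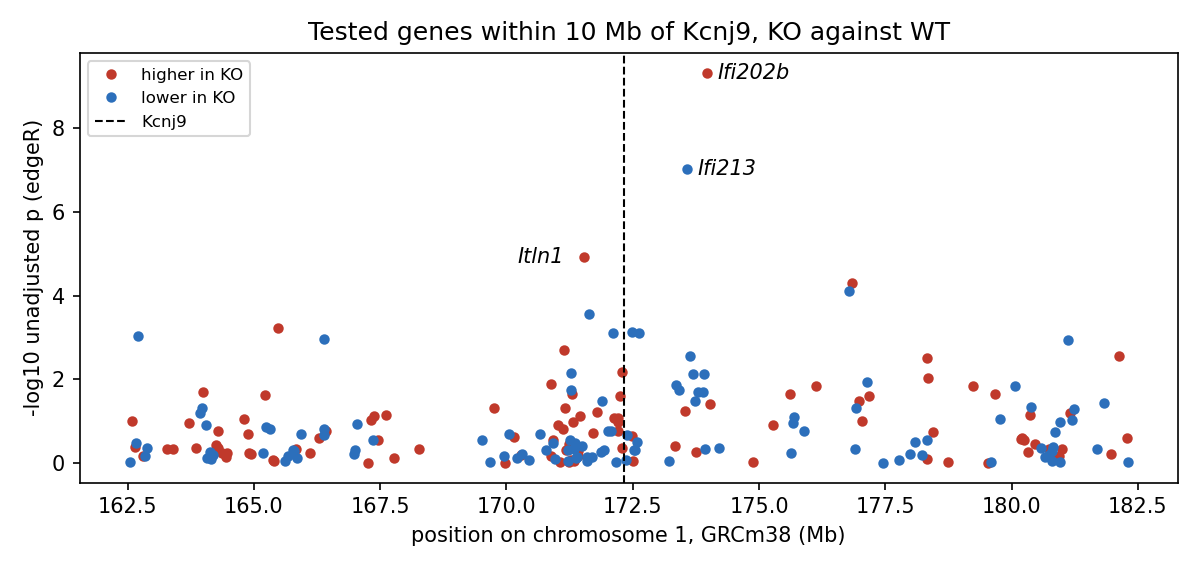
Negative log10 of the unadjusted edgeR p value (vertical axis) of the 215 tested genes within 10 Mb of Kcnj9, by position on chromosome 1 in GRCm38 (horizontal axis, Mb). Points are genes, red where higher and blue where lower in KO, and the dashed line is Kcnj9: Ifi202b and Ifi213 stand above all others, followed by Itln1.

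None of the osteoblast maturation, osteocyte and mineralization lists passed its main test. Of 20 measured genes of osteoblast maturation, 15 had negative and 5 positive log2 fold changes, with a median of -0.20 (camera adjusted p = 0.110). Runx2, the transcription factor that commits cells to the osteoblast lineage, was at 50.3 ± 6.16 CPM in WT and 37.4 ± 4.24 CPM in KO (log2 fold change -0.43, SE 0.13, edgeR adjusted p = 0.130). The matrix protein gene Tnn had a log2 fold change of -0.52 (SE 0.19, edgeR adjusted p = 0.191). Of markers chosen after their values were seen, Sp7 was at 65.2 ± 9.04 CPM in WT and 50.4 ± 9.60 CPM in KO. Col1a1 was at 8126 ± 3190 and 6899 ± 1942 CPM, and Bglap, which encodes osteocalcin, at 229 ± 75.9 and 297 ± 114 CPM. None of the 3 passed (edgeR adjusted p = 0.242, 0.758 and 0.578). Of 16 osteocyte genes, 13 were lower and 3 higher, with a median of -0.27 (camera adjusted p = 0.108). Ptprz1, a receptor phosphatase of osteocytes, had a log2 fold change of -0.56 (SE 0.14, edgeR adjusted p = 0.0999) and was the 1 osteocyte gene that passed when adjusted over the list alone. The mineralization list had 10 of 13 genes lower, a median of -0.20 (camera adjusted p = 0.459), with Mgp at 0.66 and Phospho1 at -0.45. No gene of these lists passed edgeR over all genes, 4, 1 and 1 had an unadjusted p under 0.05, and DESeq2 called 0, 1 and 0. The osteoblast maturation list passed, lower in KO, without WT replicate 3 (median -0.26, camera adjusted p = 0.00600) or KO replicate 1 (-0.32, 0.00214). The osteocyte list did so without WT replicate 2 (-0.32, 0.0338), WT replicate 3 (-0.39, 0.0443) or KO replicate 1 (-0.38, 0.00266), and without the low-count filter (-0.28, 0.0452). Both also passed, lower in KO, once the trend of each library with exon length and GC content was removed (medians -0.27 and -0.29, camera adjusted p = 0.0391 and 0.0254).

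The genes of bone matrix and collagen assembly were slightly lower in KO as a group. Of 31 measured genes 25 had negative log2 fold changes, with a median of -0.19 (camera adjusted p = 0.0247, adjusted p = 0.964 with an estimated correlation). Col6a1, which encodes a chain of collagen VI, was at 131 ± 7.36 CPM in WT and 95.7 ± 10.1 CPM in KO (log2 fold change -0.45, SE 0.12, edgeR adjusted p = 0.102). Col6a3 had a log2 fold change of -0.44. In edgeR 0 genes of the list passed over all genes and 0 when adjusted over the list alone, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 3. The list's median exon length was 6099 bases. Its call was lost without WT replicate 1 (median -0.09, camera adjusted p = 0.161), WT replicate 2 (-0.14, 0.103), KO replicate 3 (-0.17, 0.0954), KO replicate 4 (-0.07, 0.173) or both replicates 4 (-0.10, 0.0723). It was also lost with the muscle score as a covariate (-0.13, 0.125), with the length and GC trend removed (-0.11, 0.188) and with the length trend alone removed (-0.14, 0.0942). Levels per library overlapped, at 7.19 ± 0.199 mean log2 CPM in WT and 7.01 ± 0.213 in KO (SD, n = 4 each, exact permutation p = 0.257).

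Osteoclast genes showed no common direction, with 9 of 19 higher and 10 lower, a median of -0.07 (camera adjusted p = 0.802), Myo1d at -0.40 (edgeR adjusted p = 0.0960) and the sorting nexin gene Snx10 at 0.25. Factors that regulate osteoclasts had a median of -0.20 (camera adjusted p = 0.284), with the cytokine gene Csf1 at -0.34. Canonical Wnt components and targets had a median of -0.15 (camera adjusted p = 0.492), with the ligand genes Rspo3 at 0.69 and Wnt4 at 0.66. GIRK channels and Gi/o signalling, the list that holds the partners of the deleted subunit, had a median of 0.02 (camera adjusted p = 0.792). Gabbr1, a subunit of the GABA-B receptor, was at 41.8 ± 2.34 CPM in WT and 29.7 ± 1.90 CPM in KO (log2 fold change -0.49, SE 0.10, edgeR adjusted p = 0.0728). It was the 1 gene of that list that passed when adjusted over the list alone. Myo1d passed when adjusted over the osteoclast list alone, and the other lists of this paragraph had no such gene. In these 4 lists edgeR called 0 genes over all genes, 2, 1, 6 and 3 had an unadjusted p under 0.05, and DESeq2 called 1, 0, 1 and 1.

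Nuclear genes of oxidative phosphorylation were higher in KO as a group. All 36 measured genes had positive log2 fold changes, with a median of 0.59 (camera adjusted p = 9.14e-29, adjusted p = 0.964 with an estimated correlation). Ndufa2, a subunit of complex I, was at 111 ± 10.3 CPM in WT and 208 ± 45.4 CPM in KO (log2 fold change 0.91, SE 0.16). Ndufb5, another subunit of that complex, had a log2 fold change of 0.75 (SE 0.14), and both had an edgeR adjusted p of 0.0728. In edgeR 0 of the 36 passed over all genes and 29 when adjusted over the list alone, 29 had an unadjusted p under 0.05, DESeq2 called 25 and limma-voom 18. The list's mean level was 7.99 ± 0.204 log2 CPM in WT and 8.55 ± 0.0594 in KO (SD, n = 4 each), higher in every KO than in every WT library. The exact permutation p was 0.0286, the smallest that 4 against 4 can give, and 0.571 adjusted over 40 lists. The 13 mitochondrially encoded genes went the other way, with a median of -0.24, 10 genes lower and mt-Nd5 at -0.64, and did not pass (camera adjusted p = 0.155). They passed without WT replicate 4 (median -0.41, camera adjusted p = 0.00370), KO replicate 4 (-0.58, 1.64e-05) or both (-0.74, 5.85e-12). They also passed with limma-voom (-0.59, 0.000120) and with the muscle score (-0.63, 4.75e-05), the marrow score (-0.38, 0.00245) or a surrogate variable (-0.34, 0.0186) as a covariate. All these calls used the preset correlation. The estimated correlation was applied only to the main test, where it gave this list a camera adjusted p of 0.975. Mitochondrially encoded transcripts took 10.6 ± 1.5% of the counts in WT and 7.98 ± 2.52% in KO (SD, n = 4 each, exact permutation p = 0.114). KO replicates 1 to 3, at 7.36, 5.84 and 7.09%, lay below all WT libraries (8.46 to 11.9%). The groups overlapped through KO replicate 4, at 11.6%.

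Ribosomal protein genes were also higher in KO as a group, with 34 of 35 genes higher and a median of 0.46 (camera adjusted p = 6.66e-13, adjusted p = 0.964 with an estimated correlation). Among them, Rpl5 had a log2 fold change of 0.50. In edgeR 0 ribosomal protein genes passed over all genes and 0 when adjusted over the list alone, 22 had an unadjusted p under 0.05, and DESeq2 called 9. Fatty acid oxidation and citrate cycle genes were higher in 23 of 26 cases, with a median of 0.31 (camera adjusted p = 9.28e-06, adjusted p = 0.964 with an estimated correlation). Of these, Etfb, which passes electrons to the respiratory chain (log2 fold change 0.83, SE 0.14, edgeR adjusted p = 0.0714), and Suclg1 (0.68) passed when adjusted over the list alone. In edgeR 0 passed over all genes, 11 had an unadjusted p under 0.05 and DESeq2 called 2. The median was 0.19 without WT replicate 4 (camera adjusted p = 0.00370), and the call was lost without WT replicate 4 and KO replicate 4 together (0.17, 0.0723). Glycolysis genes were higher in 19 of 23 cases, with a median of 0.20 (camera adjusted p = 0.0443, adjusted p = 0.964 with an estimated correlation), among them the muscle isoform gene Pgam2 (0.70) and Ldhb (0.79). In edgeR 0 glycolysis genes passed over all genes or over the list alone, 4 had an unadjusted p under 0.05 and DESeq2 called 1. The list's mean level was also higher in every KO than in every WT library (exact permutation p = 0.0286, 0.571 adjusted over 40 lists). The glycolysis call was lost without WT replicate 4 (median 0.11, camera adjusted p = 0.0521), KO replicate 3 (0.19, 0.0730), KO replicate 4 (0.11, 0.130) or both replicates 4 (0.13, 0.206). It was also lost with DESeq2, limma-voom, the stricter filter and shared members left out (camera adjusted p = 0.0668, 0.0573, 0.0636 and 0.0754).

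Skeletal muscle markers, which mark tissue attached to the bone, were higher in KO in 22 of 28 cases, with a median of 0.45 (camera adjusted p = 4.60e-05, adjusted p = 0.964 with an estimated correlation). Tnni2, a fast-fibre troponin, had a log2 fold change of 0.80 (SE 0.24, edgeR adjusted p = 0.128) and Pvalb one of 0.77. In edgeR 0 muscle markers passed over all genes or over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 3. Muscle genes took 14.3 ± 2.63% of the counts in WT and 16.5 ± 2.18% in KO (SD, n = 4 each), a difference within the spread between mice (exact permutation p = 0.343). The extremes were 10.4% in WT replicate 4 and 19.3% in KO replicate 4. The muscle call was lost without both of these (median 0.18, camera adjusted p = 0.830) and with limma-voom (0.30, 0.0573). With the muscle score as a covariate the fatty acid oxidation list had a median of 0.09 (camera adjusted p = 0.404) and glycolysis one of 0.17 (0.334).

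Cell cycle genes were lower in KO in 32 of 34 cases, with a median of -0.37 (camera adjusted p = 0.0101, adjusted p = 0.964 with an estimated correlation). The list's levels overlapped, at 5.62 ± 0.503 mean log2 CPM in WT and 5.35 ± 0.322 in KO (SD, n = 4 each, exact permutation p = 0.429). Over the 8 libraries they followed those of the erythroid marker list (Pearson's r = 0.900), a list chosen for this after its values were seen. The member with the smallest p went against the list: Ube2c, a ubiquitin-conjugating enzyme of mitosis, had a log2 fold change of 0.72 (SE 0.16, edgeR adjusted p = 0.0840). Ube2c was the 1 gene that passed when adjusted over the list alone, and the kinesin gene Cenpe was at -0.57. At 380 ± 59.15 CPM in WT and 624 ± 49.1 CPM in KO, Ube2c lay far above Cenpe, at 36.1 ± 11.8 and 24.4 ± 6.2 CPM (SD, n = 4 each). Whether the Ube2c counts hold reads of an overlapping gene was not tested, so its rise may not be that of a mitotic gene. The cell cycle call was lost without WT replicate 4 (median -0.04, camera adjusted p = 0.816), KO replicate 4 (-0.23, 0.165) or both (0.08, 0.350), with limma-voom (-0.03, 0.833), with library totals (-0.48, 0.0585) and with the muscle score as a covariate (0.02, 0.882). Heat shock genes were higher in 12 of 13 cases, with a median of 0.29 (camera adjusted p = 0.0443, adjusted p = 0.964 with an estimated correlation), including the chaperone genes Hspb1 (0.98) and Hspe1 (0.64). The heat shock call was lost without WT replicate 3 (median 0.28, camera adjusted p = 0.0874), WT replicate 4 (0.24, 0.0904), KO replicate 1 (0.03, 0.615) or both replicates 4 (0.28, 0.0974), with limma-voom (0.01, 0.596), with the stricter filter (0.29, 0.0636) and with a surrogate variable (0.29, 0.0524). In edgeR 0 genes of either list passed over all genes, 2 and 3 had an unadjusted p under 0.05, DESeq2 called 1 and 0, and 0 heat shock genes passed when adjusted over the list alone.

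Of the 40 lists, 8 passed with the preset correlation, 6 higher and 2 lower in KO, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05. Each of the 35 splits of the 8 libraries into 4 and 4 gave at least 8 lists by the preset test. The exact permutation test of list levels passed 0 lists after adjustment, where oxidative phosphorylation and glycolysis had an unadjusted p of 0.0286. DESeq2 statistics under the preset correlation gave camera adjusted p = 1.88e-29 for oxidative phosphorylation.

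**Figure D3:**
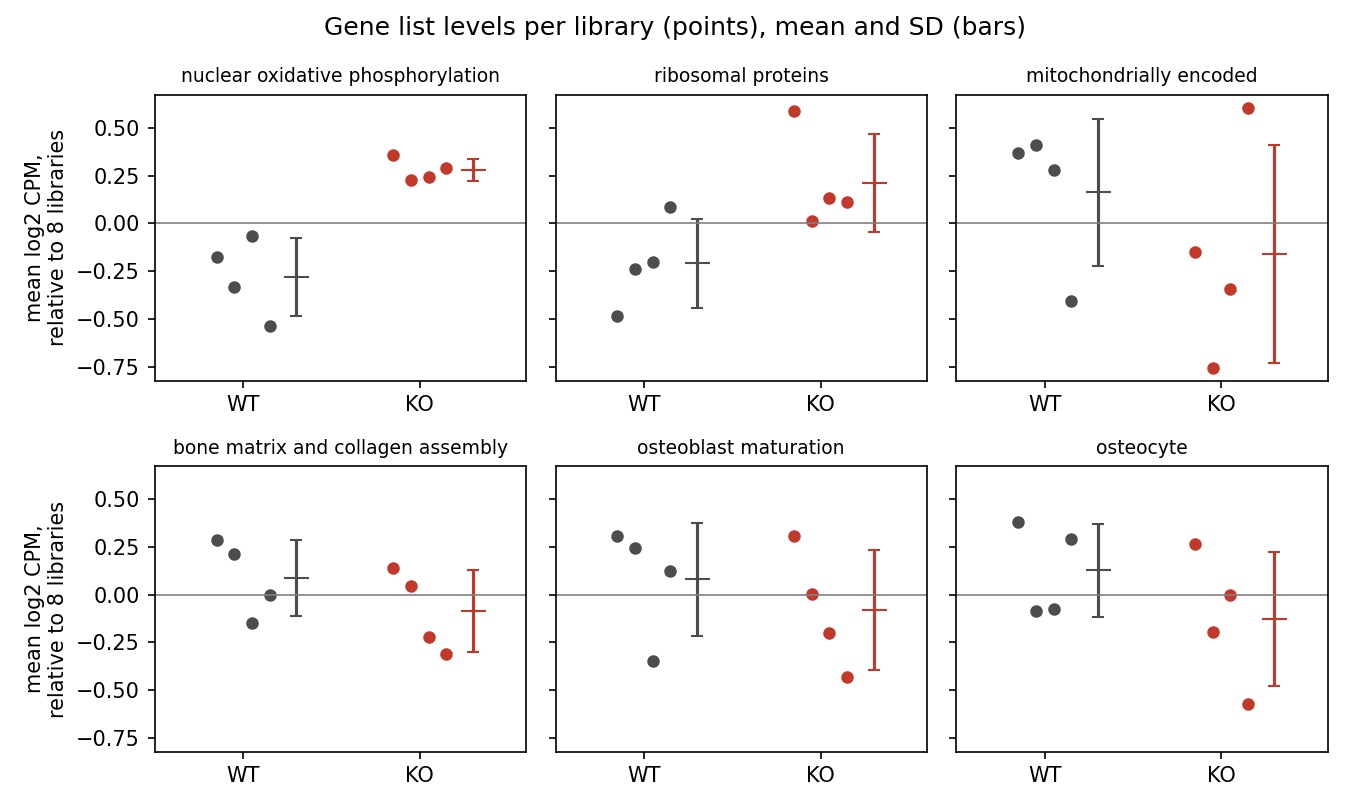
Mean log2 CPM of 6 gene lists (vertical axis, relative to the mean of the 8 libraries) in WT and KO. Points are libraries and bars are mean and SD: the oxidative phosphorylation list lies higher in every KO than in every WT library, and the other lists overlap between groups.

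Fold changes followed the exon length of the genes. Over 11597 protein-coding genes above 4 CPM, the log2 fold change fell with exon length (Spearman's rho across genes -0.493, where genes are not independent replicates). The shortest decile of genes, with 297 to 1886 exonic bases, had a median log2 fold change of 0.34, with 495 genes higher and 13 lower at an unadjusted p under 0.05. The longest decile, with 10179 to 123179 exonic bases, had a median of -0.20, with 12 genes higher and 304 lower. Within each library, the correlation of a gene's deviation from the 8-library mean with exon length was 0.308 ± 0.208 in WT and -0.253 ± 0.184 in KO (SD, n = 4 each), with no overlap (exact permutation p = 0.0286). Over all tested genes the correlation of the log2 fold change with exon length was -0.33, and 2 other splits of the 8 libraries into 4 and 4 gave larger ones, -0.396 and -0.342. Those splits kept WT replicates 1, 2 and 3 together, with KO replicate 2 or KO replicate 3 in place of WT replicate 4. The oxidative phosphorylation and ribosomal protein lists, with median exon lengths of 2101 and 1726 bases, lay at the short end of this trend. With the length and GC trend removed, the median of the oxidative phosphorylation list was 0.42 (camera adjusted p = 6.22e-22) and that of the ribosomal protein list 0.31 (4.35e-10), while the mitochondrially encoded list passed with a median of -0.51 (0.000438).

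**Figure D4:**
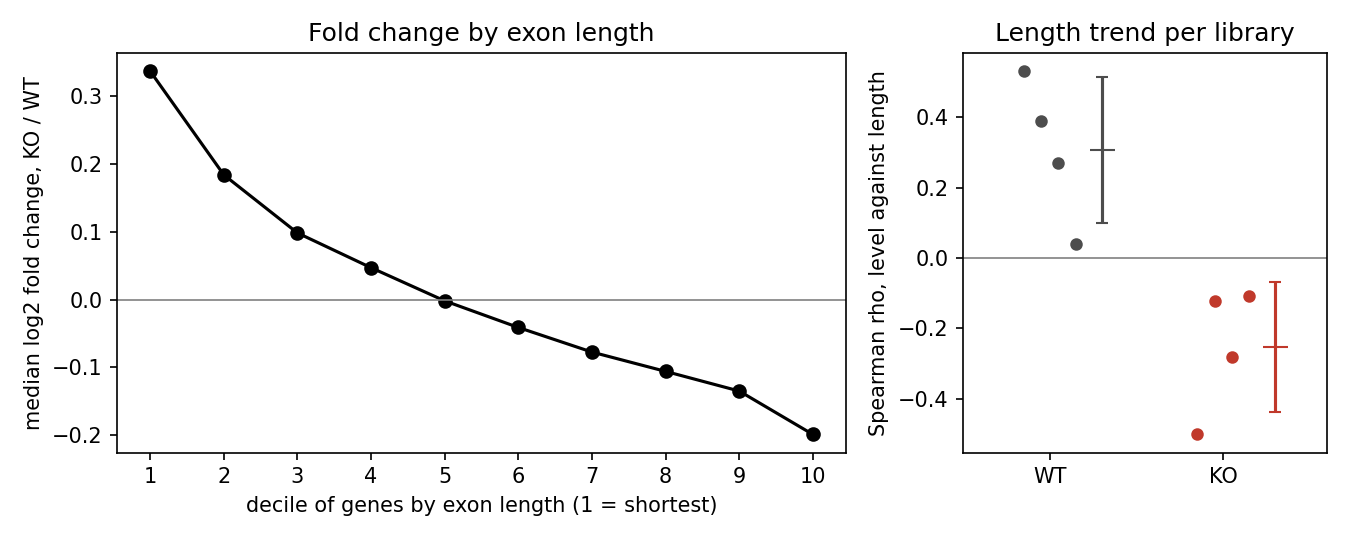
Left, the median log2 fold change of KO over WT (vertical axis) in deciles of the protein-coding genes by exon length (horizontal axis, 1 shortest), from 0.34 to -0.20. Right, Spearman's rho between a gene's deviation from the 8-library mean and its exon length (vertical axis) per library, with points for libraries and bars for mean and SD: all 4 WT libraries lie above and all 4 KO libraries below 0.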

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

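The tests of flanking DNA and of shared reads, and every value with the length and GC trend removed, were chosen only after the results they bear on were seen.

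In 11 of 143 groups of 4 libraries, 1 library stood apart from the other 3 by more than Dixon's 95% limit, where chance gives about 1 in 20. WT replicate 4 had a TMM factor of 1.18, against 0.986 to 1.00 in the other WT libraries, a mitochondrially encoded list level of -0.41 log2 CPM relative to the 8-library mean, against 0.28 to 0.41, 0.534 CPM of Kcnj9, against 0.183 to 0.205, and 14.5 CPM of Sned1, against 23.0 to 24.2. KO replicate 1 had 120.5 CPM of Romo1, 58.5 CPM of Fmc1, 122 CPM of Cops9 and 77.4 CPM of Tmem160, each above the other KO libraries, and 11.5 CPM of the Y-linked Uty, below them. Xist was at 2.32 CPM in WT replicate 1, against at most 0.256 CPM in the other WT libraries. Ifi213 had 0 CPM in KO replicate 4, against 0.0588 to 0.0642 CPM in the other KO libraries, a gap of 2 counts.

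The largest fold changes lay beside the deleted gene: of 8 genes with at least a 4-fold difference and an unadjusted p under 0.01, Ifi202b, Ifi213 and Itln1 lay within 2 Mb of Kcnj9. Reads shared between Ifi202b and Ifi213 are argued against as the whole cause, because their summed CPM was 6.92 higher in KO, with every KO above every WT library (exact permutation p = 0.0286), but reads moving among other family members stay possible, since the 13 tested genes of the cluster summed to 141 ± 30.6 CPM in WT and 114 ± 13.1 CPM in KO (SD, n = 4 each, exact permutation p = 0.229). A candidate explanation is DNA of another mouse strain carried along with the deletion, since Ifi202b levels and intelectin copy numbers are known to differ between inbred strains, and it stays open: among the other 212 genes within 10 Mb, 19 had an unadjusted p under 0.01, an odds ratio of 1.37 (95% interval 0.806 to 2.21, Fisher's exact p = 0.211). With the length and GC trend removed the odds ratio was 2.15 (1.27 to 3.43, Fisher's exact p = 0.00278). The rest of chromosome 1 then gave 1.14 (0.827 to 1.55). Among 140 bins of 20 Mb the bin that holds Kcnj9 ranked 1, against 5 without that removal. These bins included Ifi202b, Ifi213 and Itln1, which prompted the question, so the ranks are no separate evidence. An effect of the deletion on its nearest neighbours cannot be told apart from DNA of another strain. Genes within 0.5 Mb gave an odds ratio of 2.03 against those up to 10 Mb away, with an interval of 0.452 to 7.09.

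The oxidative phosphorylation and ribosomal protein lists were higher in KO, and their genes are short. The trend with exon length and GC content is argued against as the whole cause for oxidative phosphorylation. With it removed the median fell from 0.59 to 0.42, and every KO library stayed above every WT library (8.49 ± 0.0287 against 8.05 ± 0.240 mean log2 CPM, SD, n = 4 each, exact permutation p = 0.0286). The camera adjusted p of 6.22e-22 adds little, since it rests on the preset correlation. An estimated correlation was applied only to the main test, where the call was lost. For ribosomal proteins the trend stays open: with it removed the median went from 0.46 to 0.31 (camera adjusted p = 4.35e-10), while the levels of the groups overlapped before and after, with an exact permutation p of 0.0571 both times, so the overlap decides nothing about the trend. More skeletal muscle in the KO samples is argued against as the whole cause for both lists by their medians, 0.56 and 0.62 when the muscle score was a covariate. The camera adjusted p values (8.72e-14 and 2.63e-20) add little, since they rest on the preset correlation, with which every split of the libraries called lists. Levels per library were not compared with this covariate. A biological effect of the genotype and a difference in RNA quality, for which no measurement was at hand, both stay open as sources of the length trend.

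The bone matrix and collagen assembly list was lower in KO, and its genes are long. With the length and GC trend removed its median went from -0.19 to -0.11 and the camera adjusted p from 0.0247 to 0.188. With the muscle score as a covariate the median was -0.13 (camera adjusted p = 0.125). The difference of the list levels was -0.17 log2 CPM before the removal (SD 0.199 in WT and 0.213 in KO) and -0.09 after it (0.188 and 0.232), so the call ended as a difference already within the spread became smaller. The trend cannot be told apart from an effect of the genotype, because that difference lay within the spread both times. The share of muscle cannot either, because the difference lay within the spread from the start and levels were not compared with that covariate.

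Chance could not be excluded for the count of genes or of lists. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 2 genes, the real one with 2 and 1 with 86, in which KO replicate 4 and WT replicate 4 changed places. Since these libraries lie at the ends of the first principal component, that split may follow a structure of the samples apart from the genotype. It also keeps 3 WT libraries on 1 side and 3 KO libraries on the other, so it still holds much of the genotype contrast. Whether its 86 genes follow the genotype was not tested. The second principal component, with 24.9% of variance, kept the groups apart, at 19.68 to 26.55 in WT and -58.13 to -6.446 in KO. What sets the groups apart on it, the genotype or another difference between them, was not tested. At an unadjusted p under 0.05 the real split gave 3172 genes and the highest other split 3417. All 35 splits gave at least as many lists as the real 8, and the highest other gave 25.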

How the results depend on the processing

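Tests chosen only after results were seen are those without WT replicate 4 and KO replicate 4 together, with the length trend removed, with the newer quasi-likelihood method, at a threshold of 0.10 and the exact test of list levels. The count of genes (2, of which 1 higher and 1 lower) became 994 (601 and 393) with DESeq2, 705 (420 and 285) with limma-voom, 71 (53 and 18) without the low-count filter, 1113 (731 and 382) with the muscle score, 1248 (762 and 486) with the marrow score, 1328 (799 and 529) with a surrogate variable, 458 (282 and 176) without both replicates 4 and 493 (319 and 174) at a threshold of 0.10. The cause was not tested. DESeq2 and limma-voom shared 579 calls. With library totals in place of TMM, 3 genes were called, 1 higher and 2 lower, the second being Sned1. Leaving out 1 library gave 2 to 4 genes, 1 to 3 higher and 1 to 2 lower, and Ifi202b and Ifi213 passed in all 8 of these. Ifi202b passed in all 24 refits (log2 fold change 6.36 to 6.90) and Ifi213 in 23 (-6.33 to -5.57).

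With the replicate number as a block, 1 gene was called, 1 higher and 0 lower, 1703 had an unadjusted p under 0.05, and Ifi213 had an adjusted p of 0.104. Libraries that share a number did not deviate together (correlations -0.187, -0.166, -0.247 and -0.568), so no pairing by number was seen. The labels do not say what a number shares, and the correlations cannot exclude pairing.

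Near Kcnj9, 19 called genes with DESeq2 (Fisher's exact p = 0.0528) and 23 with the marrow score (0.0606) did not pass the position test, which passed in all other settings (p at most 0.0487). In many of those settings the near genes called were again only Ifi202b and Ifi213, so these passes are largely the same result. The count of 8 lists became 16 without the low-count filter, 13 with the marrow score, 13 with the length and GC trend or the length trend alone removed, 0 with an estimated correlation and 0 with the exact test, and the cause was not tested. In list means, cell cycle was at 0.030 with the muscle score and 0.10 without both replicates 4, skeletal muscle at 0.022 with the muscle score, which removes that list by construction, and monocyte and macrophage at 0.50 with the muscle score and 0.43 without both replicates 4, each with a camera direction opposite to that of the main test. Counting each list and each named gene once per setting, 48 list results and 1 gene result lost a call, 79 and 130 gained one, and 908 and 348 kept their direction and their side of the threshold, called or not. The median log2 fold change of all genes was -0.01 with TMM and -0.11 with library totals. At 30087749 to 36553713 counts per library, depth limits Kcnj9, with 0 to 23 counts per library.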

Other observations

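The removal of the length and GC trend and the omission of both replicates 4 were chosen only after results were seen. All camera values in this section rest on the preset correlation of 0.01, with which each of the 35 splits of the libraries gave at least 8 lists. The estimated correlation in the main test was far higher for some lists, at 0.965 for neutrophil precursors and 0.854 for erythroid genes, and with it 0 lists passed. The passes below are therefore weak evidence of a shift in cell types.

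Markers of blood cells that may remain in flushed bone went in different directions, and no such list passed its test in edgeR with all 8 libraries, TMM, the low-count filter and group as the only term. Erythroid genes were lower in KO in 14 of 17 cases, with a median log2 fold change of -0.45 (camera adjusted p = 0.0598), including the membrane protein genes Epb42 (-0.86) and Slc4a1 (-0.74). B cell and plasma cell genes had a median of -0.15 (0.0754), with Blk at -0.89 and Rag1 at -0.80. With the length and GC trend removed both lists passed, lower in KO, with medians of -0.49 (camera adjusted p = 0.00452) and -0.34 (0.00214). Without WT replicate 1, WT replicate 2 or KO replicate 2 the erythroid list passed (camera adjusted p = 0.00189, 8.49e-05 and 0.000692), and without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 3 the B cell list (0.0230, 0.00543, 0.00358 and 0.0285). The erythroid list also passed with DESeq2 (0.0383), with the replicate number as a block (0.0365) and without the low-count filter (0.0159), as did the B cell list without that filter (0.0292). Neutrophil precursors had 17 of 18 genes higher in KO and a median of 0.37 (0.469), which passed without WT replicate 4 (0.0296), KO replicate 4 (1.63e-06) or both (3.71e-14), with limma-voom (0.0441) and with the muscle score (1.39e-24) or the marrow score (0.0109) as a covariate. The marrow score is the mean log2 CPM of the erythroid, neutrophil precursor and B cell lists. The pass of neutrophil precursors with it is therefore no separate evidence, as the score holds their own genes. T and NK cells had a median of -0.11 (0.515), monocytes and macrophages -0.01 (0.900), haematopoietic progenitors -0.08 (0.792), and megakaryocytes and platelets 0.07 (0.792), the last passing without WT replicate 4 (0.0164), KO replicate 4 (0.0120) or both (6.43e-16). Megakaryocytes and platelets also passed with limma-voom (0.0176), the muscle score (2.01e-06) or the marrow score (0.0113). Monocytes and macrophages passed, higher in KO, with the muscle score (9.04e-06) and without both replicates 4 (0.000306).

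Stromal and vascular markers did not pass either with those settings. Marrow adipocyte genes were higher in KO in 16 of 20 cases, with a median of 0.26 (camera adjusted p = 0.0754) and the lipid carrier gene Fabp4 at 0.58, and passed without WT replicate 1 (0.000580), WT replicate 3 (0.0329), KO replicate 3 (0.00678) or KO replicate 4 (0.0319). They also passed with library totals (0.0228), without the low-count filter (0.0109), with the replicate number as a block (0.0280) and with the length and GC trend removed (0.0296). Smooth muscle and pericyte genes had a median of 0.28 (0.110), with Cnn1 at 1.14 and Tagln at 0.64, and passed without KO replicate 3 (0.00758) and without the low-count filter (0.0292). Schwann cell and neuron genes had a median of 0.23 (0.108), with the myelin gene Prx at 0.45, and passed without WT replicate 4 (0.0296) and without the low-count filter (0.0281). Periosteal and fibrous tissue genes had a median of 0.11 (0.447), chondrocyte genes -0.20 (0.703), endothelial genes -0.06 (0.847) and reticular stroma genes 0.01 (0.900). For the endothelial and reticular stroma lists the camera direction was opposite to the median, and for monocytes and macrophages the mean (0.0041) and the median (-0.0067) differed in sign.

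Of the remaining signalling and stress lists, immediate early genes had a median of 0.19 (camera adjusted p = 0.108) and passed without WT replicate 4 (2.76e-07), KO replicate 2 (0.0304) or both replicates 4 (1.35e-05). They also passed with limma-voom (0.00247), without the low-count filter (0.0281), with the replicate number as a block (0.0144) and with the muscle score (0.00341) or the marrow score (0.0263). The unfolded protein response list had a median of 0.18 (0.108) and passed without WT replicate 4 (0.0296), KO replicate 3 (0.0407), KO replicate 4 (0.00177) or both replicates 4 (0.000386). It also passed without the low-count filter (0.0263) and with the muscle score (5.37e-05) or the marrow score (0.0236). Type I interferon response genes had a median of -0.18 (0.252), with Mx2 at -0.58, and passed without WT replicate 3 (0.0443). Medians were -0.09 for the AMPK pathway (0.447), -0.10 for insulin and IGF signalling (0.746), 0.10 for inflammatory cytokines (0.792), -0.01 for BMP and TGF-beta signalling (0.802), 0.07 for the PTH and cAMP response (0.979), 0.15 for the circadian clock (0.746) and 0.11 for the glucocorticoid response (0.922). With the muscle score and without both replicates 4, the AMPK pathway (0.0185 and 0.0253, lower in KO) and inflammatory cytokines (0.00954 and 0.0294, higher in KO) passed.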
